A study of Dunaliella salina with 4 samples.

How the data were processed

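RNA sequencing of Dunaliella salina, a unicellular green alga that tolerates high salt, was analysed from 4 whole-culture libraries: 2 control cultures and 2 cultures grown in deep water from Sistan. Groups were taken from the treatment label and replicate numbers from the sample titles. The labels describe wild-type vegetative cells, total RNA extracted with a commercial reagent and a standard Illumina library preparation. They do not say whether libraries were selected for polyadenylated RNA, depleted of ribosomal RNA or strand-specific. The labels put each library in a batch of its own, so batch and treatment cannot be told apart and batch could not enter any model.

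The authors deposited raw counts, whole numbers per annotated entry, for 17872 entries in each library, and a second table of normalised values. The aligner, the counting program and the genome build are not given in the sources used here. The submitters' processing notes name R 4.5.1 and DESeq2. The deposited normalised signal values were equal to the raw counts divided by 1 factor per library, and these factors were the DESeq2 median-of-ratios size factors computed here from the raw table (largest relative difference 4.98e-15). Every entry of the deposited count table had at least 10 counts in at least 2 libraries. Control replicate 1 and both deep-water libraries held no count from 1 to 9, so that a listed 0 there can stand for up to 9 counts. Control replicate 2 held 28 values from 1 to 9, with a smallest value of 2, so its low counts were not treated in the same way before deposit. It listed 46 entries at 0, against 644 in control replicate 1 and 449 and 567 in deep water 1 and 2. Its 28 low values are too few to account for this gap, so setting counts under 10 to 0 in every library does not remove it.

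Entries are named by locus tags of the annotation of strain CCAP 19/18. Of the 17872 entry names, 14363 were equal to a locus tag of the Dunsal1 v. 2 annotation, and 3509 were a locus tag with a numeric suffix. The 17872 entries fell on 16054 locus tags, of which 1429 had more than 1 entry. What the suffix stands for is not given in the sources used here, so reads may be split between entries of the same locus tag. Neither the files nor the annotation table pairs the locus tags with gene names or functions. The gene lists fixed before the data were examined could therefore not be matched, and no pathway or gene set was tested. The annotation was used only for names, positions and for which locus tags follow each other in its order. Whether such neighbours lie on the same assembled sequence was not checked.

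Deep water was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM factors, edgeR's default filter for low counts, which left 17858 entries, and Benjamini-Hochberg adjustment at 0.05. The model held the group as its single term, over all 4 libraries. CPM values are counts relative to the TMM-scaled library size. Log2 CPM used a prior count of 2. Medians by abundance used log2 of the normalised count plus 8. The standard error of a log2 fold change is the fold change divided by the square root of the F statistic. Where a group was at 0 in both libraries, a fold is given as a bound that sets each listed 0 to 9 counts. Alternatives fixed before the data were examined were other scalings, other filters, DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1) on the deposited normalised values, edgeR's robust setting, the replicate number as a block, and each library left out. Further alternatives were chosen after seeing the data: summing suffixed entries per locus tag, equalising the treatment of counts under 10, edgeR's likelihood-ratio test, leaving out the 10 most abundant entries, and shares of counts without 5 neighbouring abundant locus tags. An entry was counted as standing apart in a library if it lay more than 4-fold outside the other 3, with at least 100 counts in that library when above and in each of the others when below. The shared replicate numbers were not taken to pair libraries, because the labels give no shared day or culture.

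The entries named in the text follow 2 clauses of a rule fixed before the data were examined. Where no entry has a gene name, the rule asked for the 2 largest rises and the 2 largest falls. Where too few entries passed the adjusted threshold, it asked for the 8 with the smallest p. Both cases held, and the rule did not say how to combine them. The choice made was, among the 8 entries with the smallest p, the 2 with the highest and the 2 with the lowest log2 fold change. Other entries named were chosen after their values were seen, and the text says so.

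The scripts were tested on simulated data for the comparison of deep water with control, with 17858 entries, of which 100 were changed 4-fold and 100 were changed 16-fold. With a dispersion of 0.02, the edgeR test recovered 100 of 100 at each size. With the dispersion estimated from the 4 libraries, it recovered 3 of the 100 changed 4-fold and 60 of the 100 changed 16-fold, with 16 false calls among 79. DESeq2 recovered 39 and 90, with 142 false calls among 271. Library totals ran from 78109607 to 149180358 counts. The counting error of single entries was not set against the spread between cultures. Wilson 95% intervals for the shares of counts reported here extended at most 0.011 percentage points to either side. They cover counting error only.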

Results

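The libraries were sequenced to ask how the transcriptome of D. salina differs between standard medium and Sistan deep water. Control cultures were kept in medium with 30 g/L NaCl, and deep-water cultures in the natural water, under a 16 h light and 8 h dark cycle at 25 ± 2 °C. The labels give no salt content for the deep water, so a difference in salt cannot be told apart from other features of the water. Each group had 2 libraries, which the design describes as biological replicates. The total counts were 78109607 in control 1, 109813468 in control 2, 127736776 in deep water 1 and 149180358 in deep water 2. Despite the larger totals, the median count per entry was lower in the deep-water libraries, at 542.5 and 483, than in the controls, at 864 and 900.

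The deep-water cultures resembled each other more closely than the controls did. Across 17858 entries, the log2 CPM of the 2 deep-water libraries correlated with a Pearson r of 0.92 (Spearman's rho 0.96), and that of the 2 controls with r = 0.79 (rho 0.85). Control 2 correlated with deep water 1 and deep water 2 at r = 0.86 and 0.87, above its correlation with control 1. Control 1 had r = 0.72 with each deep-water library. These correlations are across entries, which are not independent replicates. The biological coefficient of variation was 0.69 within the control pair and 0.39 within the deep-water pair. It can include differences in how libraries were prepared or counted, as well as differences between cultures. Among entries with at least 100 counts on the higher side, at normalised counts more than 4-fold outside the range of the other 3 libraries, control 1 stood alone at 1035 entries, control 2 at 236, deep water 1 at 62 and deep water 2 at 68.

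**Figure D1:**
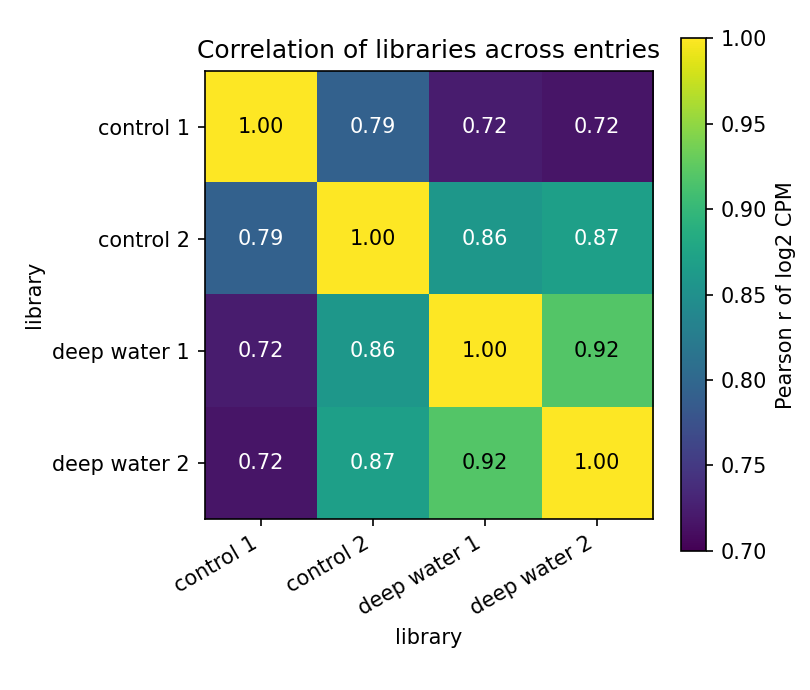
Pearson correlation of log2 CPM across 17858 entries for each pair of the 4 libraries, with libraries on both axes and r as colour and number. The highest r off the diagonal, 0.92, is that of the 2 deep-water libraries, and control 2 has a higher r with these (0.86 and 0.87) than with control 1 (0.79).

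The question of the comparison was which transcripts differ in abundance between deep water and standard medium. In deep water, a larger part of all counts fell on a small number of abundant entries. The 10 entries with the highest mean took 40.7% ± 2.3 of counts in deep water (SD, n = 2) and 19.1% ± 3.6 in the controls. By library these shares were 16.5% and 21.7% in controls 1 and 2, and 39.1% and 42.3% in deep water 1 and 2. The contrast was smaller when each library's own 10 most abundant entries were taken, at 26.5% and 26.3% in the controls and 39.6% and 43.4% in deep water. The 100 entries with the highest mean took 67.0% ± 3.7 in deep water and 45.5% ± 4.1 in the controls (SD, n = 2). When each library's own 100 most abundant entries were taken, the shares were 48.2% and 52.5% in the controls and 65.5% and 70.6% in deep water. With 2 libraries per group, the smallest p of an exact two-sided permutation test is 0.33, so that test cannot reach 0.05 here.

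**Figure D2:**
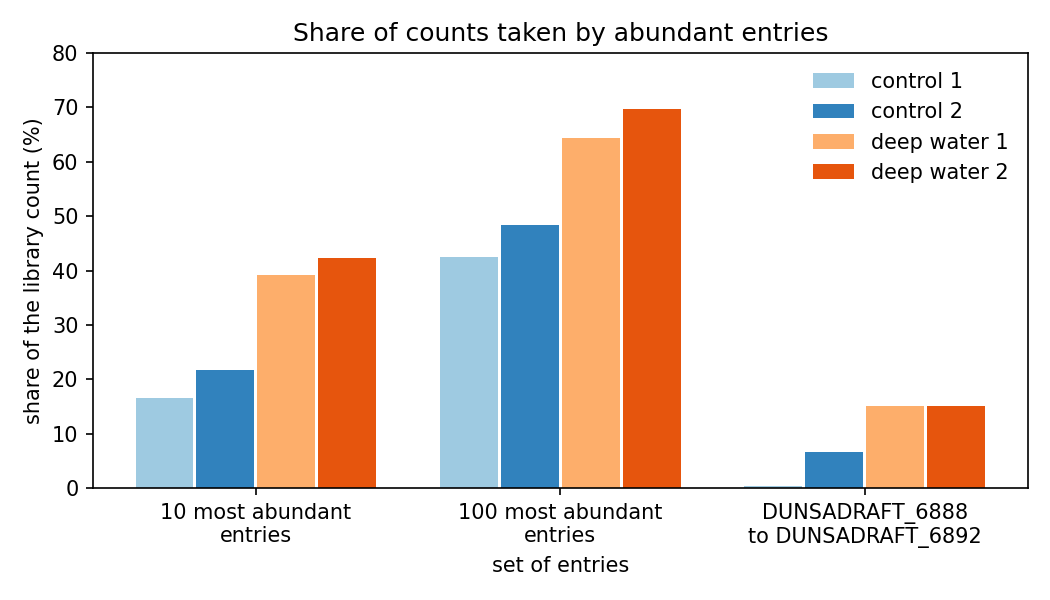
Share of each library's total count, in percent, taken by 3 sets of entries; each bar is 1 library. In all 3 sets both deep-water libraries lie above both controls, and for the 5 neighbouring locus tags control 1 (0.42%) and control 2 (6.68%) lie far apart.

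The entry with the highest mean, DUNSADRAFT_16454, took 8.22% and 5.66% of counts in controls 1 and 2 and 8.63% and 8.09% in deep water 1 and 2. Its log2 fold change was 1.66 after TMM scaling (unadjusted p = 0.016, adjusted p = 0.14 by edgeR's quasi-likelihood test). A run of 5 neighbouring locus tags, DUNSADRAFT_6888 to DUNSADRAFT_6892, took 15.1% of the counts in each deep-water library. The same 5 took 0.42% in control 1 and 6.68% in control 2. Their summed normalised count in deep water was 105-fold that in control 1 and 5.01-fold that in control 2, while control 2 itself was 21.0-fold above control 1. The difference between the 2 controls was thus larger than that between control 2 and deep water, and none of the 5 passed the test (adjusted p from 0.18 to 0.48, edgeR). DUNSADRAFT_6892 lies inside DUNSADRAFT_6891 in the annotation, so how reads were divided between these 2 can set their values. Their strands, and the assembled sequences that hold them, were not compared. In control 1 DUNSADRAFT_6892 was listed at 0 and DUNSADRAFT_6891 had 52193 counts. With these 5 locus tags removed from every library, the 10 remaining entries with the highest mean took 35.6% ± 4.7 of counts in deep water and 20.6% ± 2.8 in the controls, and the 100 with the highest mean took 61.8% ± 4.3 and 44.1% ± 1.9 (SD, n = 2). The contrast was smaller when each library's own most abundant remaining entries were taken. The top 10 then took 26.6% and 25.7% in controls 1 and 2, and 33.6% and 39.0% in deep water 1 and 2. The top 100 took 48.2% and 49.8%, and 60.1% and 66.0%, in the same order. DUNSADRAFT_16454 and the 5 neighbouring locus tags were chosen after their values were seen. What they encode is not given in the sources used here, and whether they hold ribosomal RNA or repeated sequence was not tested.

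The size of the difference among abundant entries depended on how these were chosen. Among the 1788 entries in the top 10% by mean abundance over all 4 libraries, the median log2 fold change was 0.83 (quartiles -0.39 and 1.85), against -0.21 among the other entries. Both deep-water libraries lay above both controls for 983 of these 1788 entries and below both for 223. At unadjusted p under 0.05, 700 were higher and 79 lower. The same median, from log2 normalised counts, was 1.26 against control 1 and 0.70 against control 2, and 0.26 between the 2 controls. Entries in the bottom 10% had medians of -0.34 against control 1 and -0.72 against control 2, at levels that the unequal handling of counts under 10 can reach. The median was 0.03 for the 1788 entries most abundant in the controls (-0.11 for the others) and 1.40 for those most abundant in deep water (-0.23 for the others). With each library ranked by itself, the median of its top 1788 entries lay above that of its other entries by 3.56 and 3.72 on the log2 scale in controls 1 and 2, and by 4.09 and 4.24 in deep water 1 and 2.

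**Figure D3:**
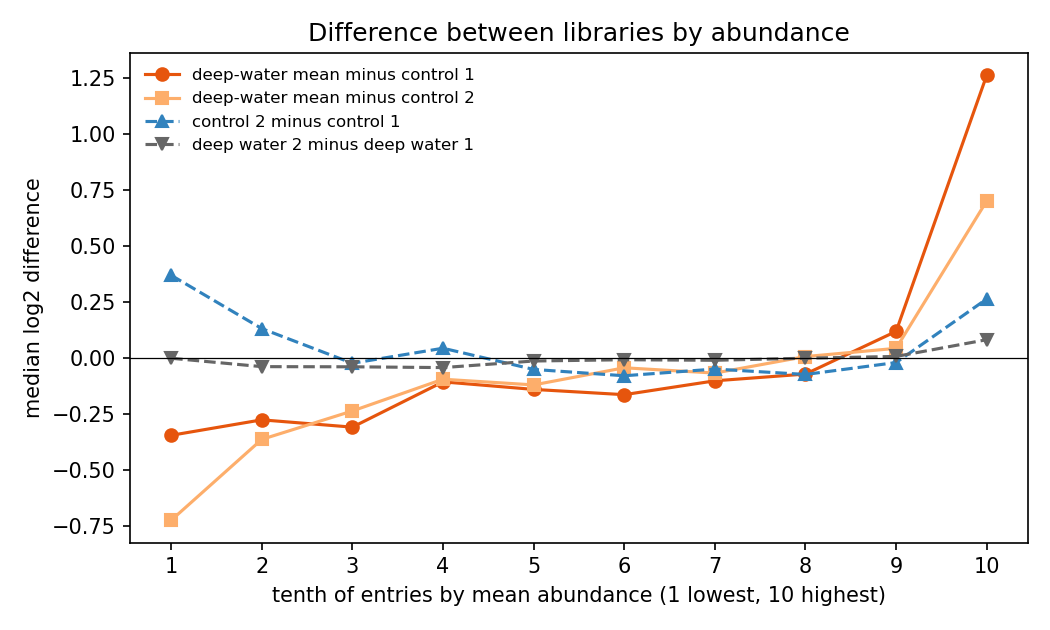
Median log2 difference of normalised counts (vertical axis) for entries sorted into 10 groups of equal size by mean abundance over all 4 libraries (horizontal axis). Solid lines compare the deep-water mean with each control, and dashed lines compare libraries of the same group. In group 10 the medians against controls 1 and 2 are 1.26 and 0.70, above the 0.26 between controls and the 0.08 between deep-water libraries.

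For single entries the test called no difference. edgeR's quasi-likelihood test gave 0 of 17858 entries at an adjusted p under 0.05, with a smallest adjusted p of 0.12. At unadjusted p under 0.05 there were 4371 entries, 2661 higher and 1710 lower in deep water. Both deep-water values lay above both control values for 5474 entries and below both for 5381. Together this was 60.8% of entries, where chance ordering of 4 libraries that vary alike gives 33.3%. The deep-water pair lay closer together than the controls, which can raise this share without any effect of treatment. The 60.8% is therefore no measure of an excess over chance. limma-voom also called 0 entries (4101 at unadjusted p under 0.05), as did limma-trend on the deposited normalised values. The DESeq2 Wald test called 3056, of which 2043 were higher and 1013 lower (5365 at unadjusted p under 0.05), and edgeR's likelihood-ratio test called 2199, of which 1480 were higher and 719 lower.

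The count of 0 also depended on which libraries were used. Without control 1 the edgeR quasi-likelihood test called 2913 entries, 1916 higher and 997 lower. Without control 2 it called 6239, 3504 higher and 2735 lower. In both fits the single control was assumed to vary like the deep-water pair. With either deep-water library left out it called 0 (1330 and 1326 at unadjusted p under 0.05). Scaling by library size alone, which does not adjust for the counts taken by the most abundant entries, called 9 entries higher and 3429 lower, and moved the median log2 fold change of all entries from -0.13 to -1.48. Directions given here are therefore relative to the TMM scaling.

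Among the 8 entries with the smallest p, the 2 with the highest log2 fold change were DUNSADRAFT_1947_2 and DUNSADRAFT_6348. DUNSADRAFT_1947_2 was listed at 0 in both controls and had 4133 and 2075 counts in deep water, or 35.4 ± 14.1 CPM (SD, n = 2). Under TMM scaling, this is at least 585-fold higher when each listed 0 is set to 9 counts (unadjusted p = 7.8e-05, adjusted p = 0.12, edgeR). DUNSADRAFT_1947_1, the other entry of this locus tag, had 148 and 67.3 CPM in the controls and 91.2 and 110 CPM in deep water, with a log2 fold change of -0.10. DUNSADRAFT_6348, the sole entry of its locus tag, had 1.91 ± 0.37 CPM in control and 17.5 ± 3.9 CPM in deep water (SD, n = 2), a log2 fold change of 3.19 ± 0.40 (SE; unadjusted p = 0.00046, adjusted p = 0.12, edgeR). Scaled by library size alone, it was 1.82.

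The 2 entries with the lowest log2 fold change were DUNSADRAFT_5067_3 and DUNSADRAFT_1835_1. DUNSADRAFT_5067_3 had 1240 and 847 counts in the controls, or 7.06 ± 2.08 CPM (SD, n = 2), and was listed at 0 in both deep-water libraries, at least 67.4-fold lower on the same basis (unadjusted p = 0.00018, adjusted p = 0.12, edgeR). DUNSADRAFT_5067_2, of the same locus tag, had a log2 fold change of 0.59 (adjusted p = 0.62, edgeR). DUNSADRAFT_1835_1 had 41.6 ± 1.5 CPM in control and 3.46 ± 1.15 CPM in deep water (SD, n = 2), a log2 fold change of -3.59 ± 0.43 (SE; unadjusted p = 0.00037, adjusted p = 0.12, edgeR), or -4.99 scaled by library size alone. DUNSADRAFT_1835_2 lay in the same direction at -2.10, and DUNSADRAFT_1835_3 in the opposite direction at 2.03, listed at 0 in control 2. As 3 of the 4 named entries share a locus tag with other entries, how reads were divided between these can set their values.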

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

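With edgeR's quasi-likelihood test the count of entries past the adjusted threshold stayed at 0 with DESeq2 or upper-quartile factors, without the filter on low counts or with a stricter one, and with the robust setting. It was also 0 with limma-voom and with limma-trend on the deposited values (pseudocounts 1 and 5, and no filter). It was 3438 with library size alone, 3056 with DESeq2 and 0 to 6239 when each library was left out. At a size of at least 2-fold these counts were 3438, 3053 and 0 to 6120. Of the alternatives chosen after seeing the data, edgeR's likelihood-ratio test gave 2199 at either size, and summing suffixed entries, equalising counts under 10, requiring 10 counts in all 4 libraries and leaving out the 10 most abundant entries gave 0. The count at unadjusted p under 0.05 was 4371, 8222 with library size alone, and 1326 to 8463 when each library was left out. The fit with the replicate number as a block called 0 entries, with 3769 at unadjusted p under 0.05; within-group deviations of same-numbered libraries correlated at 0.07, and the numbers were not taken as pairs. Library size alone differs from TMM by its construction; for the other differences the cause was not tested. The 4 named entries kept their direction in every alternative run for them. They were chosen by smallest p in these same data, so a kept direction is no independent support. Entries with a suffix have no value of their own once summed per locus tag, so that alternative was not run for them. The log2 fold change ran from 1.82 to 3.40 for DUNSADRAFT_6348 and from -4.99 to -3.29 for DUNSADRAFT_1835_1, with 1.82 and -4.99 from library size alone. The alternatives gave adjusted p from 3.3e-11 to 0.61 for DUNSADRAFT_1835_1, from 1.6e-08 to 0.61 for DUNSADRAFT_6348, from 4.7e-31 to 0.61 for DUNSADRAFT_1947_2 and from 9.3e-17 to 0.61 for DUNSADRAFT_5067_3. No alternative was run for gene lists, because none could be matched to the locus tags. In simulated data at about the depth of these libraries, with a dispersion of 0.02, the edgeR test recovered 100 of 100 entries changed 4-fold. The changed entries had a mean above 100 counts. For entries with fewer counts, depth as a limit was not tested.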

Other observations

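Of the tests below, the one without the 50 most abundant entries and the one of neighbours that do not overlap were set before their results were seen, and the others were chosen afterwards. When deep water was set against each control alone with edgeR's quasi-likelihood test, 1635 entries were called higher against both controls and 344 lower against both, while 142 were called in opposite directions. Lists of these lengths drawn independently would share 376 and 153. In 10 simulations with no effect, which kept the shared deep-water libraries, the means were 3.4 and 2.9. The simulations gave every library the same dispersion for an entry. In the data the biological coefficient of variation was 0.69 within the control pair and 0.39 within the deep-water pair. The simulations therefore cannot say how much overlap a more variable lone control would give. Part of the excess over independent lists can come from the deep-water libraries that both fits share, and each fit assumes that its lone control varies like the deep-water pair. The entries higher against both controls are a list to follow up once the locus tags have names.

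Control 2 lay nearer the deep-water libraries than control 1 did. With counts summed per locus tag and at least 100 counts in all libraries, the controls' r was 0.79 and the deep-water pair's was 0.97. Control 2 then had r = 0.82 and 0.84 with deep water 1 and 2, and control 1 had 0.70 with each. This argues against the floor on low counts and the splitting of suffixed entries as the whole cause. Over all entries control 2 had 0.86 and 0.87 with deep water and 0.79 with control 1. The floor and the splitting thus stay open as part of the cause. A swap of a control and a deep-water label is argued against by the deep-water pair's r of 0.92, with 0.87 the highest of the other pairs. Deep-water RNA or reads mixed into control 2 stay open: control 2 lay a median 0.27 of the way from control 1 to deep water among entries at least 4-fold higher in deep water and 0.84 of the way among those at least 4-fold lower, but this difference of 0.56 decides nothing, because both sets were chosen by control 1's own values. Because the labels give 4 batches for 4 libraries, batch and culture differences cannot be told apart. A single mislabelled control also stays open. So does a difference in how the reads of control 2 were counted or shared out. Control 2 listed 46 entries at 0, against 644 in control 1 and 449 and 567 in deep water 1 and 2. Its entries of the same locus tag also differed less from each other, as given below.

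The top 10% of entries by mean abundance over all 4 libraries lay higher in deep water than the rest (median log2 difference 0.90), but the difference was 0.03 for the top 10% ranked by the controls, so the ranking may set much of its size. With each library ranked by itself, the lowest deep-water gap between top and other entries lay 0.38 above the highest control gap, more than the 0.16 between libraries of a group, which argues against the ranking as the whole cause. In the ranking over all 4 libraries the difference was 0.75 to 1.50 above the rest in the 4 pairs of a deep-water and a control library, which argues against a single library. Without the 50 most abundant entries the median was 0.87, which decides little, since so few of 1788 entries can hardly move a median. An effect of the deep water and a difference in library preparation or batch both stay open.

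Neighbouring locus tags differed alike between deep water and control. Across 13697 neighbouring pairs the Pearson r of the log2 difference was 0.11 (permutation p = 1e-04, the smallest that 10000 permutations can give). It was 0.12 in pairs that do not overlap, which argues against reads shared by overlapping locus tags. The permutation shuffled locus tags within a fixed difference between libraries, so its p concerns annotation order and not the deep water. Control 2 minus control 1 gave an r of 0.030 over the same pairs (permutation p = 0.001, 1000 permutations). In pairs that do not overlap, the r for control 2 minus control 1 was 0.028 (bootstrap 95% interval 0.011 to 0.046). This lay below the interval of 0.097 to 0.133 for deep water minus control. The 2 differences are unlike, as the latter averages 2 libraries on each side and the former sets single libraries against each other. The lower r therefore does not decide whether reads that run on into the next locus tag are the cause. For deep water minus control the r was 0.17 in pairs closer than the median gap and 0.064 in the others. For control 2 minus control 1 it was 0.059 and -0.004, so that run-on reads stay open as a cause in close pairs. Pairs were taken by annotation order and rising start position. Whether both locus tags lie on the same assembled sequence was not checked, and the gap has no meaning for pairs that do not. Regulation shared by neighbouring genes may be a candidate explanation. Tandem copies that share reads stay open too, as no sequence was used here. So does a difference in library preparation or batch.

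Between deep water and control 4371 entries had an unadjusted p under 0.05 by edgeR's quasi-likelihood test, and the highest of the other splits of the 4 libraries into pairs gave 282. Of the 3 splits, 1 gave as many entries, the real one, and 3 splits are too few for a share under 0.05.

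Entries of the same locus tag differed less from each other in control 2 (median CV 0.09) than in control 1 (0.21) and the deep-water libraries (0.24 and 0.26). These medians cover 1307 locus tags in control 1, 1346 in control 2, 1225 in deep water 1 and 1198 in deep water 2. The sets differ because a mean of at least 100 counts was required within each library. Whether the reads of control 2 were counted or shared out differently was not tested.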
